A study of Mus musculus with 6 samples.

How the data were processed

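Cells were taken from the dorsal telencephalon (the future cerebral cortex) of mouse embryos at embryonic day 14.5 that carried 1 copy of GFP knocked into the Tis21 (Btg2) locus. Per the labels' protocols, dissociated cells were stained with a DNA dye, cells with a DNA content between the unreplicated and the fully replicated amount were sorted as S-phase cells, and these were separated into Tis21-GFP positive and Tis21-GFP negative cells. Per the series' design text, each replicate drew on 30 hemispheres from 15 embryos and about 200000 sorted cells, and the 3 replicates used were chosen by the authors from a larger number of independent experiments. The rule of that choice is not given in the sources used here. Per the labels, 50 ng of total RNA was amplified, labelled with Cy3 and hybridised to a 1-colour Agilent array, giving 3 arrays per group and 6 arrays in all.

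The deposited scanner files hold intensity values per spot, made with Agilent Feature Extraction 10.7.1.1 per the file headers. The processed intensity is the spot's brightness after the background and detrending steps of that software, per the file headers, with no scaling between arrays. The authors' deposited value table holds log2 values that correlated with the log2 processed scanner intensity of the same array at 0.99948 or above across probes, and the arrays' quantiles differed by at most 0.0013. The median of each of its 6 columns was 4.661. These values were read as uncentred log2 values, quantile normalized across arrays, from the values alone, since the steps behind them are not given in the sources used here.

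Each array held 62976 spots, of which 59305 were not controls and represented 55681 probes. Control spots and spots marked as outliers by the scanner software were left out, and between 118 and 191 non-control spots per array carried such a mark. No spot was saturated on any array (0 spots). Replicate spots of a probe were averaged on the log2 scale. From each array's log2 processed intensity, the 75th percentile over non-control probes was subtracted. That percentile lay between 234 and 374 intensity units, and between 51.2% and 56.2% of probes were well above background. A probe was kept when it was well above background on all 3 arrays of at least 1 group. The number of arrays limits the precision.

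Probes were named by matching the accession in the scanner file, without its version, to a RefSeq gene table of assembly GRCm38.p6, from which no coordinates were taken. Of the 55681 probes, 26370 were named, covering 19988 symbols, and 29311 were unnamed here, of which 16194 carried only a genomic region of the array's design, build mm9. A gene was represented by its probe with the highest mean over the 6 arrays. Among 3440 genes with several tested probes, 1 had probes called in opposite directions. After the filter, 13132 genes were tested. The 6 files were checked for identical values, and 0 pairs were identical.

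Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Signed differences are Tis21-GFP positive minus negative on the log2 scale, given with the moderated SE. A 2-fold subset required a log2 difference of at least 1 in size. Where a probe was well above background on no array of the dimmer group, the fold is given as a lower bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of its own value and the lowest signal among probes well above background. The 20 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with at least 5 measured members required. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with the other genes, whereas fry asks whether its members move, on balance, 1 way.

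The genes named were set by a rule fixed before the data were examined, as were the groups, tests, gene lists and all other settings not stated to be added later. The rule took 14 genes of interest, the 12 largest differences in each direction among called genes with an established symbol, no overlap between groups and signal well above background on all 3 arrays of the brighter group, and up to 4 called members with the smallest adjusted p of each list. Where a list had no called member, the rule took up to 2 with the largest moderated statistic. Other genes are named as chosen after their values were seen. Some genes that the rule took are not reported here.

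The labels give both groups the replicate numbers 1 to 3. Deviations from the group means across genes correlated at 0.23, 0.13 and 0.37 between same-numbered arrays, and the highest correlation with another number was 0.06. On this check same-numbered arrays resemble each other, and they are called pairs below. The main fit took no block. All 6 arrays lay on 1 slide and came from 1 scan, so neither could be used as a block. For replicates 1 to 3, positive arrays lay in slide columns 3, 1 and 3 and negative arrays in columns 4, 2 and 4. Column and group therefore cannot be told apart. Both arrays of a number lay side by side, in slide rows 1, 2 and 2. Slide position and a shared source therefore cannot be told apart as the reason for the resemblance. The median intensity before scaling was 27, 23.4 and 20.6 on the positive arrays and 32.7, 33 and 29.5 on the negative arrays. The 75th percentile was likewise lower on each positive array than on the negative array of its number.

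Other settings, tried 1 at a time, changed the background correction, the scaling between arrays, the filter on dim probes, the treatment of several probes, the blocks, the variance model, the source of the values and the list test, and left out each array in turn. The planned normexp correction, with an offset of 50, was run on the median spot signal because the files used here have no mean spot signal column. Where 5 other scalings are counted below, they include this correction and the authors' processed values. The filter and the choice of a gene's probe were repeated under each setting, so the tested genes and a gene's probe could differ. Testing each probe as its own feature, and the 12 further gene lists, were added after seeing the data. The fit was tested on simulated data in which 200 of 13132 genes were changed for this comparison. It recovered 2.39% of genes changed by a log2 difference of 0.5, 55.5% of those changed by 1 and 90.6% of those changed by 2, and 5.39% of calls were false. The real comparison called 3403 genes, far more than were changed in the simulation, so its adjusted threshold allowed larger unadjusted p. The recovered shares therefore describe the simulated setting and not the real comparison. Figures were drawn with matplotlib 3.10.9.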

Results

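Gene expression was measured on 6 1-colour arrays in S-phase cells of the embryonic day 14.5 mouse dorsal telencephalon. Tis21-GFP marks neural progenitors that have switched to neuron production, and the series title concerns the shortening of S phase at that switch. There were 3 arrays of Tis21-GFP positive cells and 3 of Tis21-GFP negative cells. Probes well above background numbered between 28522 and 29292 on the positive arrays and between 29329 and 31283 on the negative arrays. Correlations across genes lay between 0.983 and 0.992 within groups and between 0.954 and 0.972 across groups.

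Btg2, the locus that drives the sorted reporter, was higher in Tis21-GFP positive cells by a log2 difference of 0.77 ± 0.17 (SE, n = 3 per group, adjusted p = 0.0139). Its scaled log2 signal was 1.61 ± 0.26 in positive and 0.84 ± 0.15 in negative cells (SD, n = 3). Eomes, a transcription factor of intermediate progenitors, was higher by 3.42 ± 0.24. Vtn, which encodes vitronectin, was at least 24.5-fold lower in positive cells, where its probe was not well above background, and its log2 difference was -2.56, smaller in size than that bound, with normexp background on the median spot signal. Of 13132 genes, 1687 were higher and 1716 lower in positive cells, and 375 were at least 2-fold higher and 985 at least 2-fold lower. The groups did not overlap for 6141 genes (46.8%), against 10% by chance. The median log2 difference of all tested genes was 0.115. Genes were called against 0, and differences and list medians are given without subtracting that shift unless stated. Calls were 49.6% higher, against 65.8% with median centring, 29% with the 75th percentile taken over probes detected on all 6 arrays and 39.4% with the authors' processed values. Without Tis21-GFP negative replicate 1, Btg2 had a log2 difference of 0.685 and did not pass (adjusted p = 0.0623, range over the alternatives 0.00375 to 0.0623). The number of higher genes was 761 without Tis21-GFP negative replicate 1, 780 without Tis21-GFP negative replicate 3 and 1057 without Tis21-GFP positive replicate 1.

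**Figure D1:**
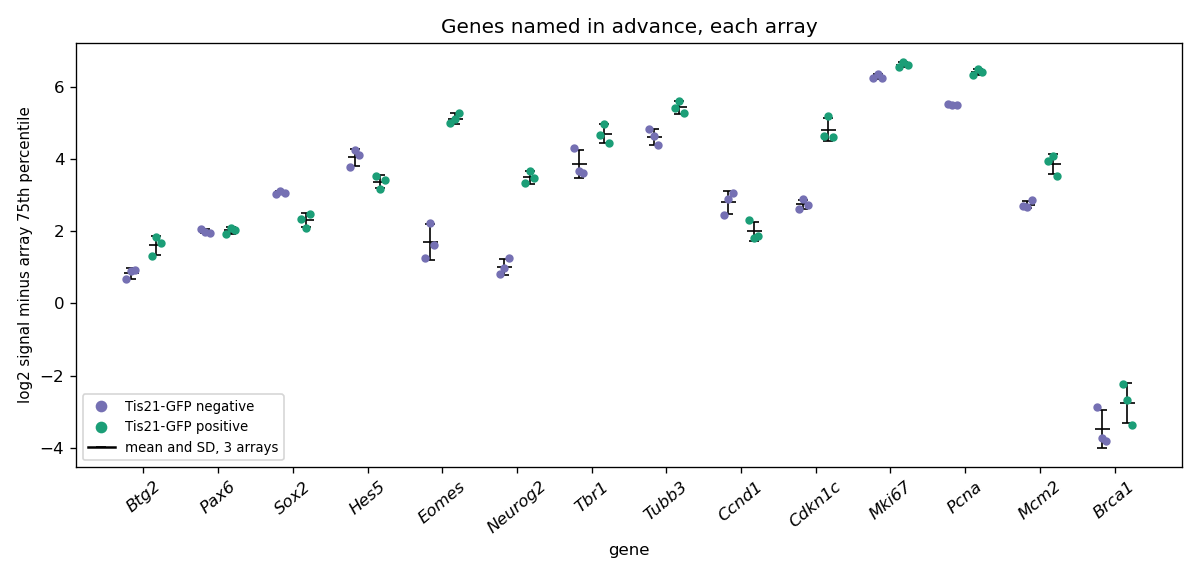
Scaled log2 signal (vertical axis, log2 signal minus the array's 75th percentile) of the 14 genes named in advance, with a point per array and bars for the mean and SD of 3 arrays in Tis21-GFP negative and positive cells. Eomes, Neurog2 and Cdkn1c stood higher in positive cells by log2 differences of 3.42, 2.48 and 2.07, and Pax6 differed by 0.02.

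The largest increases in positive cells included Eomes (3.42 ± 0.24, adjusted p = 0.000183), Kif26b (3.42 ± 0.29), the vesicular glutamate transporter Slc17a6 (3.19 ± 0.21), Gcg (3.16 ± 0.21) and the somatostatin receptor Sstr2 (3.11 ± 0.23), all well above background in both groups, although Gcg stood at 1.73 with normexp background on the median spot signal. Thrb, a thyroid hormone receptor, was at least 4.92-fold higher, Grin2c at least 5.71-fold, Ripply3 at least 4.9-fold, Cpxm2 at least 4.86-fold, Tacr1 at least 3.57-fold, Foxd3 at least 3.23-fold and Them5 at least 2.27-fold, each not well above background on any negative array. Most of the largest decreases were in genes not well above background on any positive array. Beyond Vtn, these included Col3a1 (at least 18.5-fold lower), Ctla2a (at least 14.6-fold), Pdgfrb (at least 9.33-fold), Rgs5 (at least 7.91-fold), Itga11 (at least 6.84-fold), Itgb3 (at least 5.61-fold), Ednra (at least 5.39-fold), Tlr12 (at least 5.16-fold) and Lum (at least 4.82-fold). Of these, Col3a1 and Lum belong to the fixed list of meningeal and mesenchymal markers. Pdgfrb and Rgs5 belong to that of endothelial cells and pericytes. Nid1, also of the mesenchymal list, was well above background on 1 of the 3 positive arrays, with a log2 difference of -3.53 ± 0.47. Lower markers of other cell types are taken up below. The bounds hold for the main setting and not for every other one. With normexp background on the median spot signal, which adds an offset of 50, all 22 bounds of named genes exceeded the fitted difference. Rgs5 stood there at -1.34 and Nid1, which has no bound, at -1.45. Without Tis21-GFP positive replicate 1, Thrb had a log2 difference of 2.01. Its probe was chosen again there, and that value came from the other of its 2 tested probes. The probe used above was even across the positive arrays (-1.893, -1.963 and -1.942). In that setting, 2 of the 22 bounds exceeded the fitted difference. So did 2 with each of quantile normalization, median centring and the authors' processed values. The number was 1 without Tis21-GFP negative replicate 1 and 1 without Tis21-GFP positive replicate 2.

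Genes of intermediate progenitors and neurogenic commitment were higher in positive cells. Of 25 measured members, 22 rose and 1 fell (23 and 2 adjusted over the list alone), with a median log2 difference of 2.41 (camera adjusted p = 3.52e-13, and adjusted p = 0.13 with an estimated correlation). The proneural factor Neurog2 rose by 2.48 ± 0.17 (adjusted p = 0.000158), the RNA-binding protein gene Elavl2 by 2.34 ± 0.14 and Hes6 by 2.08 ± 0.14. The member that fell, named after its value was seen, was Kif26a at -0.98. Genes of radial glia, the apical progenitors that line the ventricle, were lower. Of 27 measured members, 21 fell and 1 rose (21 and 4 adjusted over the list alone), with a median of -1.18 (camera adjusted p = 8.93e-10, and adjusted p = 0.14 with an estimated correlation). The glutamate transporter gene Slc1a3 fell by 2.12 ± 0.18 (adjusted p = 0.000294), the endothelin receptor gene Ednrb by 2.40 ± 0.24, Ptprz1 by 2.37 ± 0.23 and Psat1 by 1.42 ± 0.13. Sox2 fell by 0.76 ± 0.14 (adjusted p = 0.00764) and the Notch effector Hes5 by 0.68 ± 0.17 (adjusted p = 0.0224). Pax6 had a difference of 0.02 ± 0.12 (adjusted p = 0.937), whose sign was negative under 4 of the 5 other scalings, without Tis21-GFP positive replicate 2 (-0.02) and without Tis21-GFP negative replicate 3 (-0.01). The member that rose, named after its value was seen, was Emx1 at 1.12. Markers of microglia and of mesenchyme were also lower in positive cells, with medians of -2.38 and -2.76. Hes5 did not pass with median centring (-0.50), with no filter on dim probes (-0.68), without Tis21-GFP negative replicate 2 (-0.58), without Tis21-GFP positive replicate 2 (-0.57) or without Tis21-GFP negative replicate 3 (-0.65).

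Genes of postmitotic cortical neurons went both ways. Of 30 measured members, 10 rose and 9 fell (10 and 10 adjusted over the list alone). The neuronal splicing factor gene Rbfox3 rose by 2.15 ± 0.16 (adjusted p = 0.000183), the semaphorin co-receptor gene Nrp1 by 2.29 ± 0.23 and the transcription factor gene Neurod6 by 2.03 ± 0.23. Stmn4, a microtubule regulator, fell by 1.45 ± 0.17 (adjusted p = 0.000913). Tubb3, a neuronal tubulin, rose by 0.82 ± 0.17 (adjusted p = 0.00972) and Tbr1, a factor of early-born deep-layer neurons, by 0.83 ± 0.22 (adjusted p = 0.0299). Among those that fell, Stmn2, Mapt, Syt1 and Cntn2, chosen after their values were seen, had differences of -1.56, -1.60, -1.60 and -1.66. The list's median was 0.17 while camera's direction was downward (adjusted p = 0.916, and adjusted p = 0.97 with an estimated correlation), and the median was negative under 3 of the 5 other scalings and without Tis21-GFP positive replicate 2 (-0.03). Tubb3 did not pass with quantile normalization (0.54) or the authors' processed values (0.53). Tbr1 did not pass with quantile normalization (0.57), the authors' processed values (0.57), the 75th percentile over probes detected on all 6 arrays (0.66), no filter on dim probes (0.83) or the mean of a gene's probes (0.51). Tbr1 also did not pass without Tis21-GFP positive replicate 1 (0.84), without Tis21-GFP negative replicate 2 (0.73), without Tis21-GFP positive replicate 2 (0.69) or without Tis21-GFP negative replicate 3 (0.71).

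Genes of DNA replication licensing and the replication fork were higher in positive cells. Of 52 measured members, 32 rose and 0 fell (40 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 5.56e-10, and adjusted p = 0.12 with an estimated correlation). Fen1, a flap endonuclease of lagging-strand synthesis, rose by 1.33 ± 0.12 (adjusted p = 0.000357), the helicase cofactor gene Cdc45 by 1.18 ± 0.14, Chaf1b by 0.99 ± 0.12 and the primase gene Prim1 by 0.90 ± 0.12. Mcm2, a subunit of the replicative helicase, rose by 1.11 ± 0.17 (adjusted p = 0.00262) and the sliding clamp gene Pcna by 0.90 ± 0.12 (adjusted p = 0.00156). The list's median was 0.34 with quantile normalization and with the authors' processed values.

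Genes of homologous recombination and the Fanconi pathway rose in 8 of 35 measured members and fell in 0 (4 and 0 adjusted over the list alone). Their median was 0.30 (camera adjusted p = 0.017, and adjusted p = 0.26 with an estimated correlation). Fancf rose by 0.90 ± 0.15 (adjusted p = 0.00467) and Fancd2 by 0.78 ± 0.14. Brca1 had a difference of 0.72 ± 0.34 that did not pass (adjusted p = 0.146), and it passed with the replicate block or array row as a block, at the same difference. The call for this list was lost without Tis21-GFP positive replicate 1, at a median of 0.26. Without Tis21-GFP positive replicate 3, Brca1 passed at 1.02, and without Tis21-GFP positive replicate 1 it stood at 0.46 and did not pass. The median of the recombination list was 0.13 with the 75th percentile over probes detected on all 6 arrays, 0.17 with the authors' processed values, 0.18 with quantile normalization and 0.49 with median centring. Mismatch, base and nucleotide excision repair genes rose in 8 of 37 members and fell in 0 (6 and 0 adjusted over the list alone), and the list did not pass (median 0.20, camera adjusted p = 0.0633). It passed without Tis21-GFP negative replicate 2 (0.24) and without Tis21-GFP positive replicate 3 (0.28). The glycosylase gene Neil3 rose by 0.64 ± 0.14 (adjusted p = 0.0139), a call not made with quantile normalization (0.46), the 75th percentile over probes detected on all 6 arrays (0.46) or the authors' processed values (0.45). Of 30 checkpoint and p53 target genes, 6 rose and 3 fell (11 and 4 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.22). The value of this list ran from 0.12 to 0.48 over the alternatives. Trp53inp1 rose by 1.52 ± 0.24 and Sesn1 by 1.05 ± 0.13, whereas Pmaip1, which encodes the pro-apoptotic protein Noxa, fell by 2.20 ± 0.30 and Phlda3 by 0.87 ± 0.15. Pmaip1 was well above background on 2 of the 3 positive arrays and stood at -0.85 with normexp background on the median spot signal.

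Regulators of G1 and the G1-S transition rose in 10 of 27 members and fell in 3 (10 and 3 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.0111, and adjusted p = 0.26 with an estimated correlation). The Cdk inhibitor gene Cdkn1c rose by 2.07 ± 0.19 (adjusted p = 0.000332), the retinoblastoma gene Rb1 by 1.55 ± 0.12, E2f1 by 1.48 ± 0.14 and the cyclin E gene Ccne1 by 1.14 ± 0.15. The 3 that fell were the D-type cyclins, Ccnd1 at -0.80 ± 0.21 (adjusted p = 0.0257) and, named after their values were seen, Ccnd2 at -0.59 and Ccnd3 at -0.83. Ccnd1 did not pass with median centring (-0.62), with no filter on dim probes (-0.80), without Tis21-GFP negative replicate 2 (-0.75), without Tis21-GFP positive replicate 2 (-0.71), without Tis21-GFP negative replicate 3 (-0.68) or without Tis21-GFP positive replicate 3 (-0.73). Genes of G2 and mitosis rose in 14 of 39 members and fell in 0 (27 and 0 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 9.43e-07, and adjusted p = 0.38 with an estimated correlation). Top2a rose by 0.91 ± 0.17, Wee1 by 0.87 ± 0.17 and the kinesin gene Kif11 by 0.75 ± 0.14. With quantile normalization, the 75th percentile over probes detected on all 6 arrays and the authors' processed values, the medians were 0.23, 0.20 and 0.23 for G1 and G1-S regulators and 0.25, 0.29 and 0.25 for G2 and mitosis. Mki67 had a difference of 0.33 ± 0.12 that did not pass (adjusted p = 0.0828) and passed with a variance trend and robust fit at the same difference. Over the alternatives, the Mki67 difference ran from 0.06 to 0.51, with adjusted p up to 0.735.

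Notch pathway genes fell in 8 of 22 members and rose in 5 (11 and 6 adjusted over the list alone), with a median of -0.37 that did not pass (camera adjusted p = 0.0927). Over the alternatives, which include the mean of members in place of the median, the Notch value ran from -0.55 to -0.16. The ligand genes Dll1 and Dll3 rose by 2.51 ± 0.19 and 2.62 ± 0.19 and the glycosyltransferase gene Mfng by 2.93 ± 0.21, whereas the receptor gene Notch3 fell by 2.13 ± 0.14. Receptors and targets of FGF and Wnt signalling fell in 16 of 26 members and rose in 1 (17 and 1 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 1.21e-08, and adjusted p = 0.055 with an estimated correlation). The receptor genes Fgfr1 and Fgfr3 fell by 1.12 ± 0.13 and 1.24 ± 0.15 and Tcf7l1 by 1.27 ± 0.13, and Nkd1, a Wnt antagonist, rose by 1.25 ± 0.16. Genes of apical junctions and polarity fell in 9 of 23 members and rose in 2 (10 and 3 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.0111, and adjusted p = 0.13 with an estimated correlation). The apical polarity gene Crb2 fell by 2.01 ± 0.20 and Patj by 1.07 ± 0.16, and Pard3 rose by 0.94 ± 0.14. The second member that rose, named after its value was seen, was Ctnnb1 at 0.45. The median of the apical junction list was -0.25 without Tis21-GFP positive replicate 2, -0.18 with no filter on dim probes, -0.21 with median centring and -0.22 with normexp background on the median spot signal. With the mean of a gene's probes, Fgfr1 had a difference of -0.70 and Patj of -0.55. Markers of microglia and of mesenchyme were lower in the same cells as these lists, with medians of -2.38 and -2.76.

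Markers of other cell types were mostly lower in positive cells. Of 18 microglia and macrophage genes, 16 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of -2.38 (camera adjusted p = 1.09e-12, and adjusted p = 0.17 with an estimated correlation). Trem2 fell by 2.83 ± 0.26, Aif1 by 2.44 ± 0.22 and the complement gene C1qb by 1.77 ± 0.18. Of 12 meningeal and mesenchymal genes, 11 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -2.76 (camera adjusted p = 5.31e-09, and adjusted p = 0.13 with an estimated correlation), and the collagen gene Col4a1 fell by 3.04 ± 0.27. Of 14 endothelial and pericyte genes, 7 fell and 0 rose (8 and 1 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 0.000176, and adjusted p = 0.12 with an estimated correlation). Esam fell by 1.54 ± 0.19, and Abcc9 was at least 4.29-fold lower. With normexp background on the median spot signal, the medians were -1.16 for microglia, -1.34 for mesenchyme and -0.27 for endothelial cells and pericytes, with Trem2 at -1.73, C1qb at -1.08, Col4a1 at -1.90, Esam at -0.60, Epor at -0.67 and Sox8 at -1.32. For probes detected on all 6 arrays, those of mesenchyme and of endothelial cells and pericytes were -1.49 and -0.38, and the mesenchyme median was -1.73 with no filter on dim probes. Of 11 erythroid genes, 2 fell, Epor by 1.40 ± 0.20 and Tal1, which was at least 2.05-fold lower (3 fell and 0 rose adjusted over the list alone). Tal1 did not pass with normexp background on the median spot signal. The erythroid median was -0.63 (camera adjusted p = 0.0374, and adjusted p = 0.44 with an estimated correlation), and its call was lost with the replicate block (adjusted p = 0.0525, range over the alternatives 0.00978 to 0.442), without Tis21-GFP negative replicate 3 (-0.47) and without Tis21-GFP positive replicate 3 (-0.002). The erythroid median was -0.98 without Tis21-GFP positive replicate 1 and -0.20 with no filter on dim probes. Lists that did not pass were those of ventral telencephalon and interneurons (median -0.20, 2 of 15 rose and 5 fell, also adjusted over the list alone, camera adjusted p = 0.133), of Cajal-Retzius cells, cortical hem and choroid plexus (median -0.22, 1 of 9 rose and 2 fell, also adjusted over the list alone, camera adjusted p = 0.243) and of the oligodendrocyte lineage (2 of 10 rose and 3 fell, 3 and 3 adjusted over the list alone, camera adjusted p = 0.307). The last had a median of 0.00 and a mean of -0.50, and its median was negative under 1 of the 5 other scalings, with no filter on dim probes (-0.05) and without Tis21-GFP negative replicate 2 (-0.12). The GABA transporter gene Slc32a1 fell by 1.70 ± 0.22. Ebf3 rose by 2.35 ± 0.42 and Rspo1 fell by 1.46 ± 0.27. Of the oligodendrocyte list, Sox8 fell by 2.18 ± 0.19, Cspg4 was at least 6.37-fold lower and Mbp rose by 0.93 ± 0.17. Mbp did not pass with the mean of a gene's probes (0.55). Without Tis21-GFP negative replicate 2 the interneuron list passed (-0.36), its median was 0.05 without Tis21-GFP negative replicate 1 and 0.14 without Tis21-GFP positive replicate 2, and without Tis21-GFP negative replicate 3 the Cajal-Retzius list passed (-0.75).

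Genes of dissociation stress and the immediate early response fell in 11 of 22 members and rose in 1 (12 and 2 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 8.07e-05, and adjusted p = 0.26 with an estimated correlation). The heat shock gene Hspa1a fell by 2.02 ± 0.18 (adjusted p = 0.000303), Nr4a1 had a difference of -1.53 ± 0.18 and Klf4 of -1.25 ± 0.18. The member that rose, named after its value was seen, was Ier5 at 0.69. The list's median was -0.48 with normexp background on the median spot signal. In these cells the markers of microglia and of mesenchyme were lower too, with medians of -2.38 and -2.76. Of the 20 lists, 13 passed with the preset correlation, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.055 and 7 had an unadjusted p under 0.05. With fry, 15 passed.

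**Figure D2:**
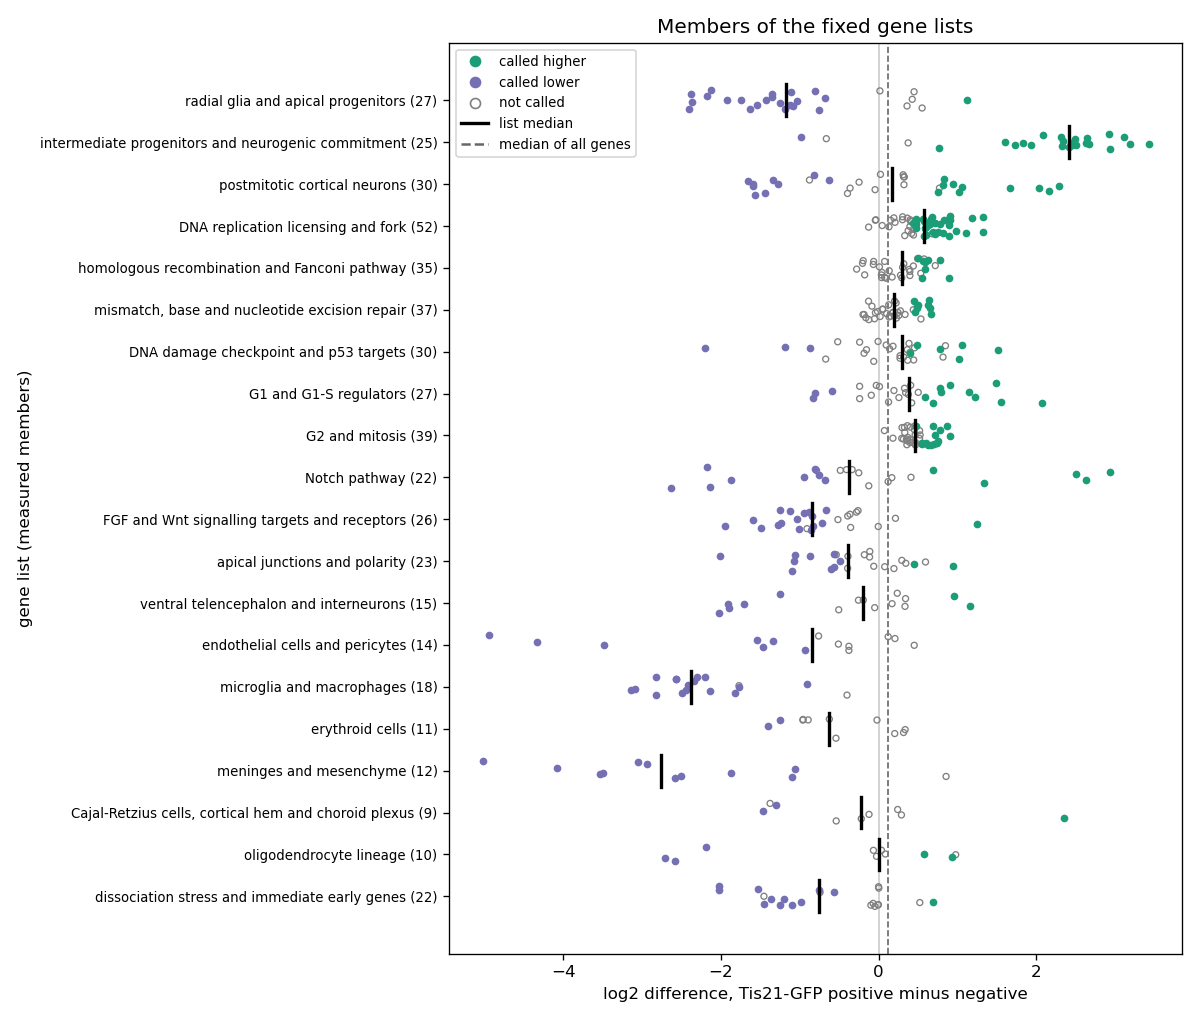
Log2 difference (horizontal axis, Tis21-GFP positive minus negative) of each measured member of the 20 fixed lists, with a point per gene, filled where called, a black bar at each list's median and a dashed line at the median of all genes, 0.115. Intermediate progenitor genes had a median of 2.41, radial glia genes of -1.18 and microglia genes of -2.38.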

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

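The tests of other splits and of mature neuron genes were set before their results were seen, although the number of genes called for the real grouping was already known. The tests of other cell types, of array scaling, of the cell cycle lists and of interneuron genes were chosen after the results were seen, and so was the use of unnamed probes.

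Signal was present in probes that carry only a genomic region and entered no comparison above. Of 5785 such probes tested, 214 were higher and 365 lower in Tis21-GFP positive cells, which is 10% called against 19.7% of 17258 named probes. All 3 probes of a forward-strand region on chromosome 5 from 123439974 to 123448354 (build mm9) were higher, with log2 differences between 2.26 and 2.53, and so were all 3 of an overlapping reverse-strand region from 123440192 to 123451767, with differences between 1.87 and 2.64. All 3 probes of a reverse-strand region on chromosome X from 18734106 to 18744367 were lower, with differences between -3.04 and -2.08.

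Of the 10 splits of the 6 arrays into 3 and 3, the real one called 3403 genes and the highest of the others called 0. Only 1 split gave as many, and 10 splits are too few for a share under 0.05. The other 3 splits that part all 3 pairs also called 0 genes. Every split but the real one mixes positive and negative arrays in both parts. The difference between the sorts then adds to the spread within parts, which makes calls unlikely from the start. The counts of 0 therefore add little.

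Markers of microglia and mesenchyme, and 7 of 14 endothelial and pericyte genes, were lower in positive cells, although the sort took S-phase cells. By its design, the DNA gate should keep such other cells only while they replicate DNA, but the purity of the sorts was not tested. Genes of the postmitotic neuron list were well above background in both sorts. Tubb3 stood at 5.44 in positive and 4.63 in negative cells and Stmn4 at 3.92 and 5.36. A candidate explanation for the microglia genes is RNA of other cell types in the GFP-negative sort: with group and replicate means removed, residuals of the 18 genes correlated at 0.20 on average (0.56 with group means alone removed), above 98.1% of 10000 lists matched on mean signal. The same test decided nothing for 12 meningeal and mesenchymal genes (-0.02, and 0.27 with group means alone removed) or for 14 endothelial and pericyte genes (-0.07 and 0.01), for which the explanation stays open. Among abundant markers, Fn1 stood at 5.03 in negative and 3.93 in positive cells, Csf1r at 2.89 and 1.98, Ctss at 1.14 and -1.27 and Col1a2 at 0.36 and -2.14, while Itgam (4.81 and 4.41), Slc2a1 (3.61 and 3.23), Kdr (2.79 and 3.24) and Egfl7 (1.01 and 1.21) were not called. The microglia median was -1.16 or lower under 5 other scalings, and the -1.16 came with normexp background on the median spot signal, a background correction. The remaining settings gave a median of all genes between -0.059 and 0.297. They could not have brought a microglia median of -2.38 near 0, so the outcome of this test was fixed in advance. A shift common to all genes would also move the median of all genes. The values therefore argue against such a shift as the cause of the microglia median. They decide nothing on the treatment of background. A difference between progenitor types stays open as untested. Of the 18 microglia genes, 0 belong to another list, but 12 were well above background on all 3 positive arrays.

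Replication and mitosis genes were both higher in positive cells with camera's preset correlation, and neither list passed with an estimated correlation (adjusted p = 0.12 for replication and 0.38 for mitosis). Medians lay above that of all genes by 0.46 for replication (0.40 to 0.48 over the 3 pairs) and 0.35 for mitosis (0.32 to 0.40), and a shift of the sorted cells along S phase stays open, since that it would move the lists in opposite directions was assumed. The replication median stayed above that of all genes by 0.32 with quantile normalization and with the authors' values, which were read as quantile normalized. It lay 0.39 above with normexp background on the median spot signal, a background correction. These values argue against array scaling as the cause only as far as that scaling and that correction go. A single common factor, such as a larger share of cycling cells, stays open as a hypothesis, although the DNA gate of both sorts should remove cells that do not cycle: the interquartile range of the mitosis list was 0.24, at percentile 1.55 of 10000 matched lists, whose median was 0.39. The change of progenitor type that the sort selects also stays open.

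Neuron genes split, with Rbfox3 and Neurod6 higher and Stmn4 lower in positive cells. GABAergic interneurons in the negative sort stay open, although as postmitotic cells they should fall outside the DNA gate of both sorts, since the 15 measured genes of their list went both ways (median -0.20, 5 lower and 2 higher), with Sst at -2.02, Slc32a1 at -1.70, Maf at -1.25 and, well above background on 1 of the 3 positive arrays, Npy at -1.90 and Gad1 at -1.92, whose call was lost with normexp background on the median spot signal (-0.51). Older neurons that have lost GFP may contribute to the negative sort, although neurons with unreplicated DNA should fall outside its DNA gate: the median of 34 mature and synaptic neuron genes lay -0.25 from that of all genes. This met the level set in advance only narrowly (camera p = 0.047), its bootstrap interval ran from -0.49 to 0.04, and the list did not pass after adjustment (adjusted p = 0.071) or with an estimated correlation (p = 0.52). The explanation therefore stays a weak hypothesis.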

How the results depend on the processing

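No called result changed direction under any setting tried. Of the list results, 367 kept their side of the threshold, 23 lost the call and 10 gained it. Of the named gene results, 1724 kept it, 63 lost it and 4 gained it. Background signal limits the bounds, of which 19 moved and 3 did not when measured means replaced them. With normexp background on the median spot signal, all 22 exceeded the fitted difference, and of 104 called named genes 36 had differences over 1.5 times smaller. The cause of the changes below was not tested. Where an array was left out, fewer arrays, the repeated filter and the repeated choice of probes all differed from the main setting. The median of all genes was 0.297 with median centring and -0.059 with the 75th percentile over probes detected on all 6 arrays.

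The number of higher genes was 928 with the 75th percentile over probes detected on all 6 arrays, 895 with no filter on dim probes and 1119 with the authors' processed values, and ran from 761 to 1732 when each array was left out. Genes at least 2-fold higher numbered 240 and those at least 2-fold lower 397 with normexp background on the median spot signal. The first numbered 608 with median centring and the second 632 for probes detected on all 6 arrays. With each probe as its own feature, an alternative added after seeing the data, 2592 were lower, 629 at least 2-fold higher and 1610 at least 2-fold lower. With the replicate block, 2016 genes were higher and 1967 lower. Among lists and named genes the block ended the erythroid call and added that of Brca1 (0.72), and it changed no other call. Btg2 ran from 0.658 to 0.914 when each array was left out.

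With camera and an estimated correlation, calls were lost at unchanged medians for radial glia (-1.184), intermediate progenitors (2.413), replication (0.576), homologous recombination (0.304), G1 and G1-S regulators (0.377), G2 and mitosis (0.462), FGF and Wnt (-0.849), apical junctions (-0.389), endothelial cells and pericytes (-0.845), microglia (-2.376), erythroid cells (-0.625), mesenchyme (-2.765) and dissociation stress (-0.751). With fry, calls were gained for excision repair (0.199), checkpoint genes (0.294) and the oligodendrocyte lineage (0.005), and lost for erythroid cells (-0.625). Excision repair passed with median centring (0.38) and with no filter on dim probes (0.199), and the Notch pathway passed with no filter on dim probes (-0.407). The erythroid call was lost with normexp background on the median spot signal (-0.157), quantile normalization (-0.743), the 75th percentile over probes detected on all 6 arrays (-0.8), probes detected on all 6 arrays (-0.281), the replicate block (-0.625) and the authors' processed values (-0.745). When each array was left out, medians ran from 0.259 to 0.356 for homologous recombination, 0.124 to 0.281 for excision repair, -0.471 to 0.14 for interneurons, -0.98 to -0.002 for erythroid cells and -0.753 to -0.042 for Cajal-Retzius cells.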

Other observations

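The 12 lists here were added after seeing the data and tested as a family of their own, in which 6 passed with camera's preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.19). The genes named were chosen after their values were seen. BMP and TGF-beta genes were lower in Tis21-GFP positive cells, with 10 of 20 measured members lower and 3 higher and a median log2 difference of -0.59 (camera adjusted p = 0.0041). Tgfbr2, well above background on 1 of the 3 positive arrays, had a difference of -1.89, Tgfb2 of -1.56 and Smad3 of -1.34. Hippo pathway and YAP target genes were lower in 7 of 18 members and higher in 1 (median -0.28, adjusted p = 0.017), with Ccn2 at -2.95, Ccn1 at -2.75 and the transcriptional coactivator gene Yap1 at -1.45. Interferon response genes were lower in 8 of 16 members and higher in 1 (median -0.53, adjusted p = 0.002), and cholesterol synthesis genes in 4 of 23 with 0 higher (median -0.32, adjusted p = 0.0094). With an estimated correlation these lists had adjusted p of 0.19, and 0.54 for cholesterol synthesis. Markers of microglia and of mesenchyme fell further in the same cells, with medians of -2.38 and -2.76.

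Oxidative phosphorylation genes were higher in 7 of 31 members and lower in 0 (median 0.36, camera adjusted p = 0.0014). Cytoplasmic ribosomal protein genes were higher in 2 of 41 with 0 lower (median 0.33, camera adjusted p = 0.0012). With an estimated correlation neither passed (adjusted p = 0.54 for both). Among all tested genes, 1687 of 13132 were higher and the median was 0.115. The ribosomal share is below that of all genes. The added lists were not tested under other scalings, where the replication list's median fell from 0.58 to as low as 0.34. Shifts of this size may therefore depend on the scaling. BAF chromatin remodelling genes were higher in 7 of 25 members and lower in 1 and did not pass (median 0.35, adjusted p = 0.051), with Bcl7a at 1.27 and Dpf3 at least 1.42-fold lower. Polycomb and DNA methylation genes also did not pass (median 0.24, adjusted p = 0.2), with Ezh2 at 0.77, Dnmt1 at 0.71 and the de novo methyltransferase gene Dnmt3a at -1.39. Axon guidance genes of the semaphorin and ephrin families went both ways, 10 of 38 higher and 9 lower (median 0.13, adjusted p = 0.74), with Epha3 at 1.95, Plxna2 at 1.92 and Epha2 at -2.84. Voltage-gated potassium and calcium channel genes were higher in 8 of 30 and lower in 9 (median -0.32, adjusted p = 0.16), with Kcnh5 at 1.92 and Kcna1 at -2.33. Glycolysis genes were lower in 3 of 18 and higher in 0 (median -0.04, adjusted p = 0.2).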
